A study of Arabidopsis with 8 samples.

How the data were processed

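Total RNA from roots and shoot parts of 5-day-old Arabidopsis seedlings was extracted with TRIzol and sequenced on an Illumina HiSeq, per the labels' protocols. Values were supplied as 1 file per library, 8 in all, in 4 groups of 2: Col-0 root, OE-SAUR41 root, Col-0 shoot and OE-SAUR41 shoot. The values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, made by the authors per the file headers. Reads were placed on the TAIR10 build, per the submitters' processing notes. The aligner, the quantifier, its treatment of reads matching several genes, and the strand setting are not given in the sources used here. Coordinates are those of the files.

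The files list values above 0 and hold no 0, so a gene that a file does not list was taken as 0. In all, 25404 genes were listed in at least 1 library and 18000 in all 8. Locus tags of 25139 genes matched a reference gene table of assembly TAIR10.1, used for names. In the files 3635 genes share their locus with another gene, and their values are uncertain. After the values were seen, 3 genes were left out as failed estimates, because 1 library of a group did not list them while the other gave over 100 FPKM: AT2G01010, AT3G41768 and LHCB1.3 (AT1G29930), with 4132 to 16237 FPKM in the other library. The largest value beside any other unlisted gene was 9.84 FPKM. Depth per library is unknown, and no interval for counting error can be given.

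Genes with at least 1 FPKM in at least 2 of the 8 libraries were tested, 19863 in all, on log2(FPKM + 1). All 8 libraries entered 1 limma fit with 4 group means (lmFit, contrasts.fit, eBayes with trend; limma 3.58.1 in R 4.3.3), with 4 residual and 3.53 prior degrees of freedom. The contrasts were OE-SAUR41 against Col-0 in roots and in shoots, the difference between these, and Col-0 root against Col-0 shoot. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes are from limma. An exact permutation test of 2 against 2 libraries cannot go below 0.333, so none was used. The planned Fisher's exact test of the overlap of calls is not reported, because the 1 shared call was the overexpressed gene. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

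A total of 28 gene lists with 429 entries were tested as sets with limma's camera at a preset correlation of 0.01, two-sided and adjusted over the lists within a contrast. Camera with an estimated correlation and fry were run beside it. The lists were the SAUR41 subfamily, other SAUR genes, auxin response, auxin transport, expansins, xyloglucan endotransglucosylases/hydrolases, cellulose synthases, plasma membrane proton pumps and D-clade PP2C phosphatases, abscisic acid response, sodium and potassium transport, calcium sensors and transporters, nitrate uptake and reduction, iron deficiency response, phosphate starvation response, aquaporins, root hair, Casparian strip and suberin, photosynthesis, brassinosteroid, gibberellin and shade growth, ethylene, immune and jasmonate response, heat shock, glucosinolate synthesis, flavonoid synthesis, mitotic cell cycle, circadian clock, root tip and stele markers, and seed storage and oil bodies. The last list had 7 of 9 members listed, at 1.83 FPKM or less, and no member passed the filter, so 27 lists were tested. Members were also adjusted over the list alone. The relative median of a list is the median log2 fold change of its tested members minus that of all genes.

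The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, apart from what is named here as added. By that rule the text names SAUR41 and its subfamily. For roots and for shoots it names the 8 largest rises and falls among called genes whose OE-SAUR41 libraries both lay on the same side of both Col-0 libraries, with a mean of at least 5 FPKM in the higher group. For the interaction and the tissues it names 4 each way. Where a comparison called no gene, the 3 smallest p each way were named. From each list with a called member, up to 4 called members were named, and from each called list without one, the 2 with the largest absolute change.

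The alternatives chosen beforehand were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, quantile normalization, TMM scaling, no trend, a robust fit, a least absolute log2 fold change of 1, the libraries of the contrast alone, the replicate number as a block, and leaving out each library. With 1 library left in a group, it was assumed to vary like the other groups. TMM factors were computed on FPKM without count weights, trimming 30% of ratios and 5% of levels on each side. Added after seeing the data were a gene length correction, library weights, calls against each Col-0 shoot library alone, and crossed replicate numbers. The length correction removed, in each library, a lowess trend (span 0.3, 3 iterations) of the deviation from the tissue mean on log2 gene span, for the 16795 genes (84.6%) with a span of their own. It is void for lists with a span for under 80% of members: cellulose synthases (62.5%), sodium and potassium transport (76.9%), Casparian strip and suberin (73.3%), immune and jasmonate response (75.0%) and heat shock (60.0%).

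The correction was first run with lengths from the TAIR10.1 table and switched to spans from the files after its results had been seen, because the table is of another assembly. In shoots it called 149 genes (83 higher, 66 lower) over 19675 genes with the table's lengths and 125 over 16795 with the files' spans, 119 of them in both. In roots it called 3 genes either way, the same 3. Between tissues it called 16065 and 13714, with 13583 in both.

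The fit was tested on simulated data for the same 19863 genes. In roots it recovered 5% of 100 genes changed by 1 on the log2 scale and 72% of 100 changed by 2. In shoots it recovered 7% and 67%. There was 1 false call in each tissue and 0 in the interaction. The simulated noise was independent between genes, with the same spread in all libraries, and only genes above a minimum level were changed. It held neither the wider spread of the Col-0 shoot pair nor a trend with gene span. These rates therefore need not hold for the real libraries, above all in shoots.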

Results

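Gene expression was measured by RNA sequencing in roots and shoots of 5-day-old Arabidopsis thaliana seedlings of 2 genotypes, the Col-0 wild type and OE-SAUR41, a line that overexpresses SAUR41. SAUR41 is a member of the SMALL AUXIN UP RNA family, small proteins first known from transcripts that rise quickly after auxin. The 8 libraries formed 4 groups of 2. The labels did not say that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The files listed between 19573 and 23028 genes per library, with summed values from 605751 to 774506 FPKM. Read depth is unknown because the files hold FPKM values and no counts. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Tissue was the main axis of variation, with 89.2% of the variance on the first principal component.

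The replicate libraries of 3 groups were close to each other, and those of Col-0 shoots were not. Pearson's r across genes, which are not independent replicates, was 0.986 for Col-0 roots, 0.981 for OE-SAUR41 roots, 0.986 for OE-SAUR41 shoots and 0.930 for Col-0 shoots. Col-0 shoots 1 and 2 differed by at least 2-fold for 5780 of 19863 genes (29.1%), against 1.27% to 2.04% in the other groups. Their difference followed the span of the gene, with a Spearman rho of 0.61 across 16795 genes, against -0.36 for Col-0 roots, 0.31 for OE-SAUR41 roots and -0.015 for OE-SAUR41 shoots. The median difference went from -0.14 in the shortest eighth of genes to 1.41 in the longest, as the plot by gene span shows. The median log2 fold change of all genes was -0.03 in roots and -0.32 in shoots. The shoot median was -0.025 without Col-0 shoot 1 and -0.58 without Col-0 shoot 2. Quantile normalization brought it to -0.01. Gene groups are therefore described below relative to the median of all genes. A single median does not remove a difference that follows gene span. Relative medians of lists in shoots may thus still hold an effect of the span of their genes.

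**Figure D1:**
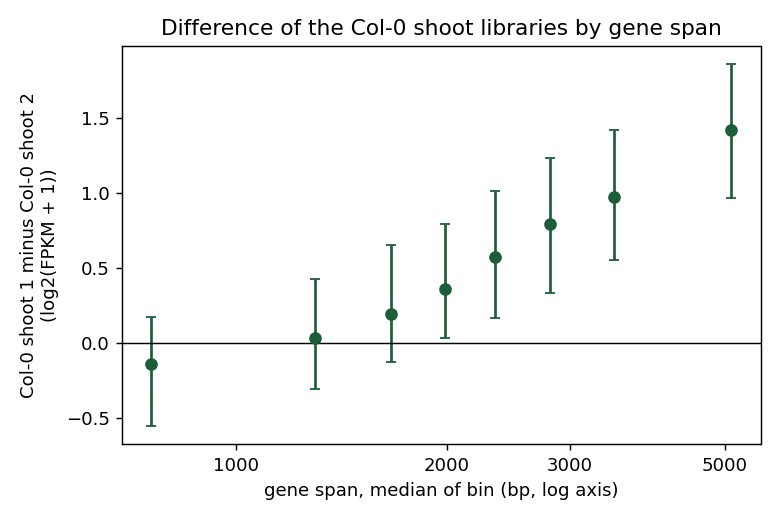
Difference between the Col-0 shoot libraries (library 1 minus library 2, log2(FPKM + 1)) against gene span in bp on a log axis, for 8 bins of genes. Points are bin medians and bars reach from the lower to the upper quartile; the median goes from -0.14 to 1.41.

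The first question was whether SAUR41 was overexpressed in the libraries labelled so. SAUR41 (AT1G16510, chromosome 1, 5644572 to 5645443, TAIR10) rose in both tissues of OE-SAUR41. In roots it stood at 6.05 ± 2.00 FPKM in Col-0 and 6333 ± 2352 FPKM in OE-SAUR41 (SD, n = 2 each). In shoots it stood at 6.61 ± 2.37 FPKM in Col-0 and 10461 ± 302 FPKM in OE-SAUR41 (SD, n = 2 each). The log2 fold change was 9.79 (SE 0.33, limma adjusted p = 8.99e-05) in roots and 10.46 (SE 0.33, limma adjusted p = 5.48e-05) in shoots. Its relatives SAUR72 and SAUR71 stood lower. SAUR72 (AT3G12830) had log2 fold changes of -1.02 in roots, where its levels were 20.2 and 18.8 FPKM in Col-0 and 8.16 and 10.2 FPKM in OE-SAUR41, and -1.84 in shoots. SAUR71 (AT1G56150) stood at 5.71 and 9.04 FPKM in Col-0 shoots and 2.55 and 3.74 FPKM in OE-SAUR41 shoots; in roots it was at most 0.442 FPKM in all 4 libraries. Neither passed over all genes. Adjusted over the list alone, the limma p was 0.0176 for SAUR72 in roots, 6.18e-04 for SAUR72 in shoots and 0.0143 for SAUR71 in shoots. The list holds SAUR41 itself, whose small p lowers the adjusted p of SAUR72. SAUR40, the remaining relative, was too low to be tested. Members of the SAUR family are close in sequence, and how the authors treated reads that match several of them is not given in the sources used here.

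**Figure D2:**
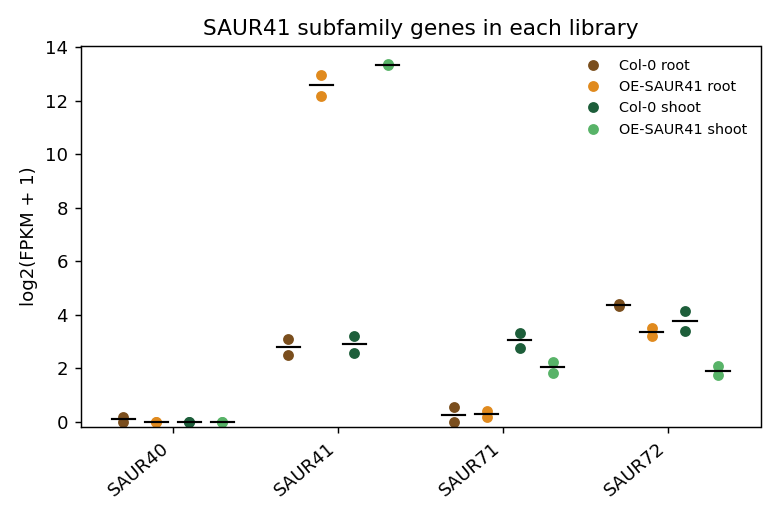
Expression of the 4 genes of the SAUR41 subfamily as log2(FPKM + 1) in each of the 8 libraries. Points are libraries, colours are groups and short lines are group means; SAUR41 lies between 4670 and 10675 FPKM in OE-SAUR41 and at most 8.29 FPKM in Col-0.

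The next comparison asked which genes differed between OE-SAUR41 and Col-0 roots. The iron deficiency genes stood lower as a group in OE-SAUR41 roots. All 13 tested members had a negative log2 fold change, and the list median lay 0.95 below that of all genes (-0.95). IRT1 (AT4G19690), the main iron transporter of the root epidermis, stood at 14.3 and 12.7 FPKM in Col-0 and 2.76 and 2.50 FPKM in OE-SAUR41, 3.99-fold lower on the log2(FPKM + 1) scale (SE 0.23 on that scale, chromosome 4, 10707426 to 10709015). IMA2 (AT1G47395), a small peptide that promotes iron uptake, stood at 12.1 and 20.9 FPKM in Col-0 and 2.41 and 1.79 FPKM in OE-SAUR41, a log2 fold change of -2.46 (SE 0.51). The bHLH factors of iron deficiency followed, with -1.92 for bHLH39 and -1.66 for bHLH38, then CYP82C4 (-1.64), IMA1 (-1.53) and the ferric reductase gene FRO2 (-0.99).

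In roots, limma called 1 of 19863 genes, SAUR41 itself. An unadjusted p under 0.05 was found for 340, fewer than the share of 0.05 that no difference at all would give. No iron deficiency gene passed over all genes; the smallest limma adjusted p was 0.0577 for CYP82C4, with 0.162 for IRT1. Adjusted over the list alone, 7 of the 13 were lower. The camera test of the list gave an adjusted p of 3.36e-29 with the preset correlation and an adjusted p = 0.0198 with an estimated correlation. Directional fry gave an adjusted p of 0.00799. With the estimated correlation, leaving out any 1 library ended the call: adjusted p rose to 0.119 and 0.236 without Col-0 root 1 and 2, 0.0587 and 0.0661 without OE-SAUR41 root 1 and 2, 0.151 and 0.152 without Col-0 shoot 1 and 2, and 0.0709 and 0.0712 without OE-SAUR41 shoot 1 and 2. It was also lost with quantile normalization (adjusted p = 0.0906), with the gene length correction (adjusted p = 0.142) and with the replicate block (adjusted p = 0.103). The relative median was -0.58 without Col-0 root 2, -1.68 with a pseudocount of 0.1, -0.42 with a pseudocount of 5, -0.52 with no filter and -1.50 with a filter at 5 FPKM.

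The number of root calls depended on the Col-0 shoot libraries, because 1 estimate of the spread was shared. The median SE was 0.304 in roots and in shoots. The interquartile range of replicate differences was 0.30 and 0.41 for the root groups, 0.34 for OE-SAUR41 shoots and 1.08 for Col-0 shoots. Root p-values may thus be too large and shoot p-values too small. Without Col-0 shoot 1 or without Col-0 shoot 2, limma called 9 genes in roots (3 higher, 6 lower), and with the 4 root libraries alone 8 genes (2 higher, 6 lower). IRT1 was among them in all 3 fits, with adjusted p = 0.0302 without Col-0 shoot 1, 0.0307 without Col-0 shoot 2 and 0.0173 in the root libraries alone. Genes singled out after their values were seen included NAS4 (AT1G56430), a nicotianamine synthase of metal transport, at 28.3 and 32.9 FPKM in Col-0 and 10.3 and 10.9 FPKM in OE-SAUR41. AT3G01345 had a mean of 20.9 FPKM in Col-0 roots and 1.19 FPKM in OE-SAUR41 roots. It was also lower in shoots, with 28.0 and 21.1 FPKM in Col-0 and 2.99 and 2.88 FPKM in OE-SAUR41 (log2 fold change -2.68). In roots, IPSP (AT5G04120, 2.16 and 2.84 against 11.1 and 11.5 FPKM) stood higher. So did SWEET11 (AT3G48740, a sucrose exporter, 5.86 and 5.95 against 12.8 and 12.7 FPKM). SWEET11 was not called with the root libraries alone (limma adjusted p = 0.272).

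**Figure D3:**
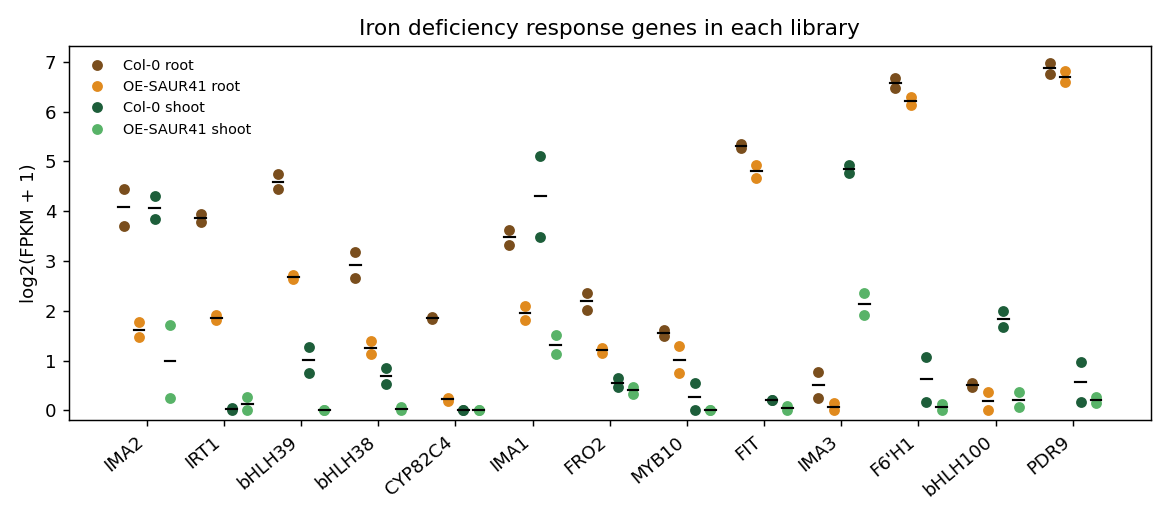
Iron deficiency response genes as log2(FPKM + 1) in each of the 8 libraries, ordered by the log2 fold change in roots. Points are libraries, colours are groups and short lines are group means; IRT1 lies at 14.3 and 12.7 FPKM in Col-0 roots and 2.76 and 2.50 FPKM in OE-SAUR41 roots.

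Lists of xyloglucan enzyme, aquaporin and cellulose synthase genes were called higher in OE-SAUR41 roots by camera, with no member called. These calls were lost with an estimated correlation (adjusted p = 0.580, 0.600 and 0.831, in this order). The estimates, 0.188, 0.704 and 0.979, came from all 8 libraries and were the same for roots and shoots. The wide spread of the Col-0 shoot pair thus entered them too. Expansin genes, also of the cell wall, had 6 positive and 16 negative values (relative median -0.06, camera adjusted p = 0.113). Of 26 genes for xyloglucan endotransglucosylases/hydrolases, enzymes that remodel cell wall xyloglucan, 21 had a positive log2 fold change (relative median 0.27, camera adjusted p = 1.88e-07; adjusted p = 0.580 with an estimated correlation). XTH18 had 0.91 and XTH19 0.77. The 18 aquaporin genes, water channels, had 17 positive values (relative median 0.33, camera adjusted p = 4.71e-10; adjusted p = 0.600 with an estimated correlation), with 0.52 for PIP2;3 and 0.49 for TIP2;1. The 8 cellulose synthase genes were all positive (relative median 0.28, camera adjusted p = 7.01e-03; adjusted p = 0.831 with an estimated correlation), with 0.44 for CESA7 and 0.36 for CESA4, which both share a locus with another gene in the files. Omitting Col-0 root 1 moved the relative median of the xyloglucan enzymes to 0.48, and omitting Col-0 root 2 moved it to 0.15 and that of aquaporins to 0.22. The cellulose synthase call was lost without Col-0 root 1 (adjusted p = 0.193), without OE-SAUR41 root 1 (adjusted p = 0.0731) and with no filter (adjusted p = 0.0669).

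Photosynthesis genes, near the floor in roots, stood lower, with all 18 values negative (relative median -0.31, camera adjusted p = 1.40e-07; adjusted p = 0.600 with an estimated correlation). RBCS2B (AT5G38420; means of 2.57 against 1.15 FPKM) and LHCB1.1 (AT1G29920; means of 4.42 against 2.13 FPKM) both had a log2 fold change of -0.70. The relative median was -0.14 without Col-0 root 1, -0.13 without OE-SAUR41 root 1 and -0.50 without OE-SAUR41 root 2. The 42 other SAUR genes were called lower (camera adjusted p = 9.97e-04; adjusted p = 0.583 with an estimated correlation) although their relative median was near 0 and members went both ways, with -1.02 for SAUR6 and 0.94 for SAUR9. The SAUR41 subfamily was called higher (camera adjusted p = 8.12e-03, and 0.580 with an estimated correlation). Of its 3 tested members SAUR41, the overexpressed gene, was the 1 called, with SAUR72 at -1.02 and a list median of 0.005. The call therefore follows from the line and says nothing about the relatives of SAUR41. Without OE-SAUR41 root 1 the calls for photosynthesis (adjusted p = 0.105) and other SAUR genes (adjusted p = 0.549) were lost. The subfamily call was lost without Col-0 shoot 1 (adjusted p = 0.109), without Col-0 shoot 2 (adjusted p = 0.101), with no filter (adjusted p = 0.411) and with the length correction (adjusted p = 0.0567).

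The other 20 lists were not called in roots. The camera adjusted p was 0.939 for auxin response, 0.143 for auxin transport, 0.113 for expansins, 0.514 for proton pumps and PP2C phosphatases, 0.161 for abscisic acid response and 0.143 for sodium and potassium transport. It was 0.167 for calcium sensors, 0.0642 for nitrate uptake, 0.659 for phosphate starvation, 0.514 for root hair, 0.720 for Casparian strip and suberin, and 0.242 for brassinosteroid, gibberellin and shade growth. It was 0.938 for ethylene, 0.0642 for immune and jasmonate response, 0.860 for heat shock and 0.0942 for glucosinolate synthesis. It was 0.113 for flavonoid synthesis, 0.855 for mitotic cell cycle, 0.723 for circadian clock and 0.706 for root tip and stele markers.

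In shoots, the comparison of OE-SAUR41 with Col-0 called 4 genes, 2 higher and 2 lower, and 2790 genes had an unadjusted p under 0.05. The shared estimate of the spread may make these p-values, and those adjusted over a list alone, too small. Besides SAUR41, GASA1 (AT1G75750, chromosome 1, 28441526 to 28442429), a gibberellin-regulated gene for a cysteine-rich peptide, rose from 112 ± 3.90 to 439 ± 9.15 FPKM (SD, n = 2 each), a log2 fold change of 1.96 (SE 0.18, limma adjusted p = 0.0390). AT2G02050 (chromosome 2, 489966 to 491995), which encodes a subunit of mitochondrial complex I, fell from 38.0 ± 3.44 to 10.6 ± 0.812 FPKM (SD, n = 2 each), a log2 fold change of -1.75 (SE 0.16, limma adjusted p = 0.0390). The remaining call, AT2G36030, lay outside the naming rule and was named after its values were seen. It stood at 2.85 and 3.52 FPKM in Col-0 shoots, was not listed in either OE-SAUR41 shoot library, and shares its locus with another gene (limma adjusted p = 0.0390). In Col-0 roots it stood at 1.19 and 0.964 FPKM, near the filter, and it was not listed in either OE-SAUR41 root library. The root difference had the same direction but did not pass (limma adjusted p = 0.596).

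Several alternatives ended these shoot calls. GASA1 (AT1G75750) was lost without each root library (adjusted p from 0.103 without Col-0 root 1, 0.105 without Col-0 root 2, 0.197 and 0.196 without OE-SAUR41 root 1 and 2) and without OE-SAUR41 shoot 1 (0.495) or 2 (0.427). AT2G02050 was lost without the same libraries (0.180, 0.176, 0.197, 0.196, 0.495 and 0.427), and both were lost with TMM scaling (0.0779 and 0.0945), which moved the log2 fold changes to 2.41 and -1.35. Both were also lost with the replicate block (0.0949 and 0.0989), with no trend (0.101 for each), with library weights (0.710 and 0.656) and with the shoot libraries alone (0.170 and 0.301), and GASA1 was lost with no filter (0.0609). The log2 fold changes stayed at 1.96 and -1.75 in these alternatives and without each root library, and were 1.94 and -1.68 without OE-SAUR41 shoot 1 and 1.98 and -1.83 without OE-SAUR41 shoot 2. With each of these 6 libraries left out, SAUR41 was the 1 call. Leaving out Col-0 shoot 1 gave 361 calls (188 higher, 173 lower) and leaving out Col-0 shoot 2 gave 9864 (784 higher, 9080 lower). Against each Col-0 shoot library alone, 211 genes were called in the same direction (79 higher, 132 lower) and 38 in opposite directions. Quantile normalization called 24 genes, 19 of them higher (79.2%, against 50% without it).

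The list of other SAUR genes, many of which promote cell expansion, was called lower in OE-SAUR41 shoots (camera adjusted p = 1.49e-03; adjusted p = 0.4997 with an estimated correlation). Of the 42 other SAUR genes, 32 had a negative log2 fold change and 19 were lower adjusted over the list alone, while none passed over all genes. Directional fry, which tests a list on its own and not against other genes, gave an adjusted p of 0.0247. SAUR16 (AT4G38860) stood at 25.9 and 44.1 FPKM in Col-0 and 9.50 and 6.59 FPKM in OE-SAUR41, a log2 fold change of -1.97, and SAUR32 (AT2G46690) at 7.11 and 5.85 against 0.737 and 1.90 FPKM (-1.73). The relative median of the list was -0.30, and -0.60 without Col-0 shoot 1. By a split chosen after the values were seen, the 12 genes assigned to tandem clusters had a relative median of -0.34. The 30 others had one of -0.024, with 12 of these lower adjusted over the list alone. Some of the 30 also lie beside another gene of the list, so the split does not set single genes apart from neighbours. The call was lost with quantile normalization (adjusted p = 0.131, relative median -0.19), and without Col-0 shoot 2 the direction turned (relative median 0.23, adjusted p = 0.259).

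Iron deficiency and clock genes were also called lower in OE-SAUR41 shoots, calls lost with an estimated correlation (adjusted p = 0.499 and 0.550). Directional fry, which tests a list on its own and not against other genes, gave adjusted p = 0.0166 and 0.135, in this order. Of 13 iron deficiency genes, 5 were lower adjusted over the list alone, and none passed over all genes. The peptide genes IMA2 (13.4 and 18.7 against 2.29 and 0.197 FPKM, log2 fold change -3.08), IMA1 (10.2 and 33.7 against 1.19 and 1.85 FPKM, -2.98) and IMA3 (26.2 and 29.6 against 4.15 and 2.76 FPKM, -2.71) led the list. Its relative median was -0.23 (camera adjusted p = 3.73e-03; adjusted p = 0.499 with an estimated correlation), and the call was lost without Col-0 shoot 2 (adjusted p = 0.656, relative median -0.08). The relative median was -0.11 without Col-0 shoot 1 and 0.03 with a pseudocount of 5. Of 11 circadian clock genes, 8 were tested, and CCA1 and LHY were among those not tested. All 8 had a negative log2 fold change and 4 were lower adjusted over the list alone: ELF4, PRR5, FKF1 and LUX. A difference in the time of harvest was not tested. ELF4 (AT2G40080), a component of the evening complex, had a mean of 84.4 ± 21.8 FPKM in Col-0 and 33.2 ± 4.58 FPKM in OE-SAUR41 (SD, n = 2 each), and a log2 fold change of -1.30, and TOC1 had -1.16. The relative median was -0.57 (camera adjusted p = 3.73e-03; adjusted p = 0.550 with an estimated correlation). The relative median was -0.36 without Col-0 shoot 1, with adjusted p = 0.0339.

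Lists of xyloglucan enzyme, aquaporin and suberin genes were called higher than other genes in OE-SAUR41 shoots, and each call was lost with an estimated correlation (adjusted p = 0.499, 0.4997 and 0.499). Lists of cellulose synthase genes (relative median -0.16, camera adjusted p = 0.489) and expansin genes (relative median 0.24, camera adjusted p = 0.819) were not called, although expansins were called lower without Col-0 shoot 1 (adjusted p = 0.00593; adjusted p = 0.407 with an estimated correlation) and higher without Col-0 shoot 2 (adjusted p = 0.00942; adjusted p = 0.619 with an estimated correlation). Of 26 xyloglucan enzyme genes, 14 had positive and 9 negative values (median 0.07), and XTH24, XTH15 and XTH6 were higher adjusted over the list alone (relative median 0.40, camera adjusted p = 2.58e-08; adjusted p = 0.499 with an estimated correlation). XTH24 (AT4G30270) stood at 71.7 and 51.8 FPKM in Col-0 and 266 and 254 FPKM in OE-SAUR41, a log2 fold change of 2.08. XTH23 had 1.81, but its Col-0 libraries lay apart, at 10.3 FPKM in shoot 1 and 1.93 FPKM in shoot 2. In OE-SAUR41 shoots XTH23 stood at 18.6 and 19.9 FPKM, so the size of its change depended on the Col-0 library. Among 18 aquaporin genes 17 were positive and PIP1;1 was higher adjusted over the list alone (0.89); TIP2;2 had 1.12. Their relative median was 0.81 (camera adjusted p = 9.19e-14; adjusted p = 0.4997 with an estimated correlation), and it was 0.21 without Col-0 shoot 1 and 1.29 without Col-0 shoot 2, and 0.37 with quantile normalization. The fatty acid hydroxylase gene CYP86A1 of suberin synthesis stood at 1.46 and 1.65 against 5.67 and 7.42 FPKM (1.56) and GPAT5 had 0.90. The Casparian strip and suberin list, with 8 positive and 7 negative values (median 0.01), had a relative median of 0.34 (camera adjusted p = 1.00e-03; adjusted p = 0.499 with an estimated correlation), and 0.09 without Col-0 shoot 1.

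**Figure D4:**
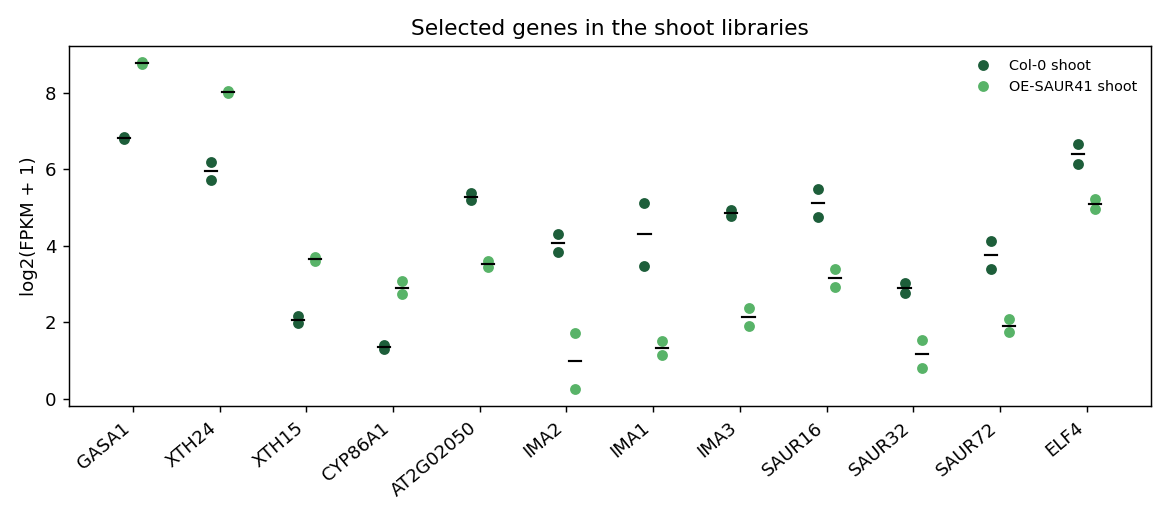
Genes of the shoot comparison as log2(FPKM + 1) in the 4 shoot libraries; the genes shown were picked after their values were seen. Points are libraries and short lines are group means; GASA1 lies at 109 and 115 FPKM in Col-0 and at 446 and 433 FPKM in OE-SAUR41.

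Photosynthesis genes were called higher in shoots (relative median 0.61, camera adjusted p = 5.25e-06, and 0.581 with an estimated correlation), with 0.67 for LHCB2.2 and 0.63 for LHCB2.1. LHCB2.2 stood at 1496 and 2961 FPKM in Col-0 shoots 1 and 2 and at 3370 and 3349 FPKM in OE-SAUR41. LHCB2.1 stood at 1739 and 3448 FPKM in Col-0 shoots 1 and 2 and at 3807 and 3761 FPKM in OE-SAUR41. Both rises thus rested mainly on Col-0 shoot 1. The relative median of the list turned to -0.04 with quantile normalization (camera adjusted p = 0.772). It was -0.14 without Col-0 shoot 1 and 1.302 without Col-0 shoot 2. Nitrate genes were called higher (camera adjusted p = 5.28e-03; 0.550 as adjusted p with an estimated correlation), with 0.50 for NIA1 and 0.43 for NRT1.1, and the call was lost with quantile normalization (adjusted p = 0.121) and without Col-0 shoot 2 (adjusted p = 0.232), where NIA1 turned to -0.12. Abscisic acid response genes went both ways, with 1.26 for RAB18 and -1.22 for KIN2 (camera adjusted p = 0.0318, called higher; adjusted p = 0.852 with an estimated correlation). Ethylene genes (0.0409 by camera; adjusted p = 0.765 with an estimated correlation) included ACS6 at -1.52 and ERF1 at 0.73. Immune and jasmonate genes (0.0294; adjusted p = 0.714 with an estimated correlation) included VSP2 at 1.72 and JAZ10 at 1.24. Glucosinolate genes (0.0188; adjusted p = 0.765 with an estimated correlation) were called higher although MYB28 had -0.97 and MYB29 had -0.72, which was 0.079 without Col-0 shoot 1. Root hair genes were called higher (0.0106; adjusted p = 0.607 with an estimated correlation) from levels of at most a few FPKM, with LRX2 at 0.70 and 0.45 against 2.11 and 2.22 FPKM and PRP3 at 0.24, which was -0.23 without OE-SAUR41 shoot 1.

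These lists were called higher relative to all genes, while their members went both ways. Negative values numbered 19 of 27 for abscisic acid, 4 of 8 for ethylene, 6 of 12 for immune, 5 of 11 for glucosinolate and 6 of 15 for root hair genes.

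Most of these weaker calls did not survive single omissions. Without Col-0 shoot 2 the adjusted p was 0.656 for abscisic acid, immune and glucosinolate genes and 0.732 for ethylene genes. Without OE-SAUR41 shoot 1 it was 0.0529 for abscisic acid, 0.0530 for immune, 0.400 for ethylene and 0.0660 for root hair genes, and without OE-SAUR41 shoot 2 it was 0.354 for ethylene. Without Col-0 shoot 1 it was 0.676 for root hair genes. Quantile normalization gave 0.121 for abscisic acid, 0.159 for immune, 0.445 for glucosinolate, 0.161 for root hair and 0.0548 for ethylene genes, and TMM scaling gave 0.766 for root hair and 0.0599 for immune genes. The relative median of the immune genes was 0.27, against 0.90 without Col-0 shoot 1 and -0.34 without Col-0 shoot 2. That of the abscisic acid genes was 0.10, against 0.35 and -0.04, and -0.15 with a filter at 5 FPKM. Root hair genes had 0.32, against 0.03 and 0.58. Without Col-0 shoot 2, nitrate genes had 0.46 against 0.72, ethylene genes 0.13 against 0.37 and glucosinolate genes 0.18 against 0.34.

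The other 14 lists were not called in shoots. The camera adjusted p was 0.486 for the SAUR41 subfamily, 0.777 for auxin response, 0.825 for auxin transport, 0.819 for expansins, 0.489 for cellulose synthases and 0.670 for proton pumps and PP2C phosphatases. Adjusted over the list alone, the expansin genes EXPA1 (-1.01) and EXPA16 (-1.69) and the calcium sensor genes CML23 (-1.24) and CML42 (-1.03) were lower. The adjusted p was 0.670 for sodium and potassium transport, 0.935 for calcium sensors, 0.777 for phosphate starvation, 0.894 for brassinosteroid, gibberellin and shade growth, and 0.670 for heat shock. It was 0.670 for flavonoid synthesis, 0.627 for mitotic cell cycle and 0.670 for root tip and stele markers.

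**Figure D5:**
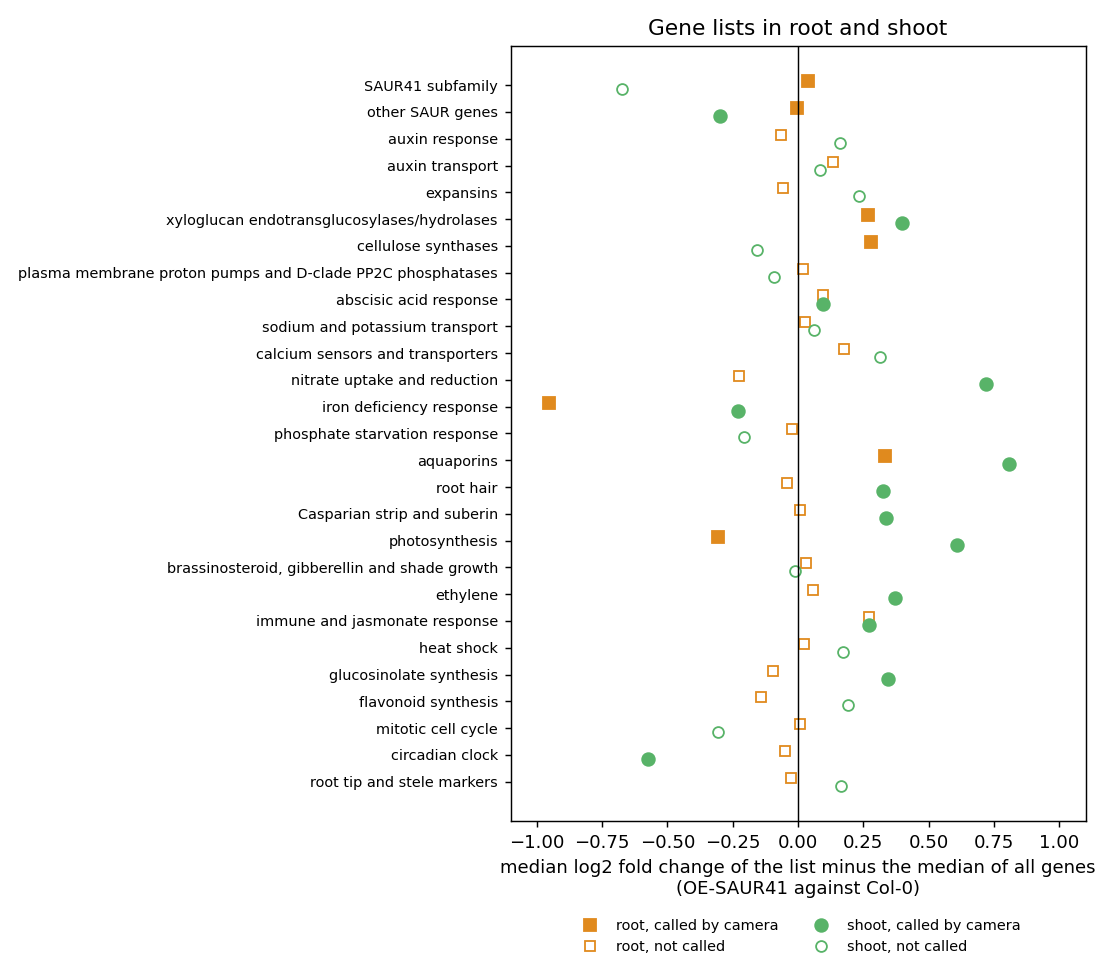
Median log2 fold change (OE-SAUR41 against Col-0) of each gene list minus the median of all genes, for 27 lists in root (squares) and shoot (circles). Filled symbols are lists called by camera with the preset correlation; the lowest is iron deficiency response in root at -0.95 and the highest is aquaporins in shoot at 0.81, which is 0.37 with quantile normalization.

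Whether the response differed between tissues was tested by the interaction of genotype and tissue. The limma interaction called 0 of 19863 genes. An unadjusted p under 0.05 was found for 948, about the share of 0.05 that no difference at all would give. The genes with the smallest p did not pass. NIT2 (AT3G44300), a nitrilase gene, stood at 2.17 and 1.62 against 9.06 and 8.80 FPKM in shoots and MLP34 (AT1G70850) at 15.8 and 21.9 against 67.5 and 63.7 FPKM; both had an interaction of 1.92 (limma adjusted p = 0.577). On the other side, AT2G02050 had -1.78 (0.577), and CDEF1 (AT4G30140), a cutinase gene, -1.61 (limma adjusted p = 0.628). CYP82C4 (limma adjusted p = 0.577) and IPSP (0.628) were measured in roots and near or at 0 in shoots. Leaving out Col-0 shoot 1 gave 1 interaction call and leaving out Col-0 shoot 2 gave 6888, and with no filter there were 2, CYP82C4 and ORF120 (ATMG00710).

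SAUR41, the overexpressed gene itself, was the 1 gene called in both tissues, so the overlap follows from the line and tests no shared response. Its interaction was 0.67 (limma adjusted p = 0.807). The overlap held 4 genes without Col-0 shoot 1 and 5 without Col-0 shoot 2. Across the 19862 other genes, which are not independent replicates, the log2 fold changes of root and shoot had a Pearson r of 0.083 and a Spearman rho of 0.040. Pearson's r was 0.194 without Col-0 shoot 1 and -0.011 without Col-0 shoot 2.

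The comparison of Col-0 roots with Col-0 shoots described the baseline and checked the tissue labels. All 18 photosynthesis genes were lower in roots, and all 15 root hair genes and 14 of 15 Casparian strip and suberin genes were higher, also with TMM scaling and with quantile normalization. DOX1 (AT3G01420), a fatty acid dioxygenase gene, stood at 1050 and 1121 FPKM in roots and 1.15 and 0.84 FPKM in shoots, a log2 fold change of 9.09 (SE 0.16, limma adjusted p = 6.75e-07). AT3G28550 (8.23), AT1G23720 (8.15) and MLP328 (7.73) followed. The light-harvesting genes LHB1B1 (-10.00) and LHCB1.2 (-9.81), the Rubisco small subunit gene RBCS-3B (-9.82) and the germin-like gene GER3 (-9.78) had the lowest values among named genes. Light-harvesting and Rubisco genes have near-identical copies, so their single values are uncertain.

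In all, limma called 13094 genes between the tissues, 10470 higher (80.0%) and 2624 lower in roots. The balance depended on scaling. The median of all genes was 0.91 as measured and 0.09 with TMM scaling, which called 4032 higher (48.2%) and 4337 lower. Without Col-0 root 1 the number of calls was 7845, and without Col-0 root 2 it was 8258.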

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

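All tests of explanations in this part were chosen after the results were seen; the tests of the difference between tissues were planned. Camera with the preset correlation gave a different genotype response in shoots and roots for 10 lists, none of which passed with an estimated correlation (adjusted p from 0.616 to 0.889). The adjusted p was 0.0133 for xyloglucan endotransglucosylases/hydrolases, 0.0429 for cellulose synthases, 1.10e-03 for nitrate uptake and reduction, 4.56e-03 for iron deficiency response, 1.10e-03 for aquaporins, 4.56e-03 for root hair, 4.56e-03 for Casparian strip and suberin, 1.73e-11 for photosynthesis, 4.56e-03 for glucosinolate synthesis and 6.01e-03 for circadian clock. Cellulose synthase and clock genes stood lower in the shoot response than in the root response, relative to all genes, and the other 8 lists higher. Iron deficiency genes went both ways, with 7 positive and 6 negative interactions. In shoots IRT1 was at most 0.201 FPKM and CYP82C4 was 0, so neither could fall there. IMA1, IMA2 and IMA3, which were measured in shoots, had interactions of -1.45, -0.62 and -2.29. The median interaction of all genes was -0.298, and it was 1.04e-04 without Col-0 shoot 1 and -0.543 without Col-0 shoot 2. Root hair genes stood at a few FPKM or less in shoots, with a median log2 fold change of 0 there. They had little room to fall with the other genes, so their call does not decide whether they responded differently. The Casparian strip and suberin list had a median of 0.01 in shoots, and 14 of its 15 genes were higher in Col-0 roots than shoots. The same limit may apply to its call. Photosynthesis genes were near the floor in roots, where the log2(FPKM + 1) scale understates changes. The limma interaction called 0 genes, with 948 at an unadjusted p under 0.05, about the share that no difference at all would give.

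For 5 of the tested genes named in the text, both OE-SAUR41 libraries lay on one side of both Col-0 libraries in roots and on the opposite side in shoots. The difference of log2 fold changes, shoot minus root, was -2.18 for SAUR16 (AT4G38860; limma adjusted p = 0.792), -1.73 for CML23 (AT1G66400; 0.807), 1.31 for LHCB2.2 (AT2G05070; 0.807), 1.14 for LHCB2.1 (AT2G05100; 0.807) and 0.66 for DOX1 (AT3G01420; 0.807), so no difference passed. SAUR16 was under 1 FPKM in all root libraries, and DOX1 under 2 FPKM in all shoot libraries. In root libraries LHCB2.2 lay between 1.15 and 4.14 FPKM and LHCB2.1 between 1.89 and 3.97 FPKM, also near the floor.

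The iron deficiency genes, lower in OE-SAUR41 roots, were set against a technical and a biological explanation. A trend with gene length is argued against as the whole cause: with that trend removed, the median log2 fold change of the 12 members with a span was -1.23 (quartiles -1.65 and -0.42), against -1.26 (quartiles -1.72 and -0.48) for the same 12 before. The camera call with the estimated correlation ended under the correction (adjusted p = 0.142), where that correlation was 0.466 over 12 members against 0.0590 over 13 before, while the preset call held. A higher iron status of the OE-SAUR41 seedlings remained open. Ferritin genes, which iron induces, had a mean log2 fold change of 0.42 over 3 genes in roots and 0.64 in shoots, with both OE-SAUR41 libraries above both Col-0 libraries for 2 of 3 genes in each tissue. No ferritin gene was called, and FER1 shares its locus with another gene. These values are consistent with a higher iron status, which was not measured, and a direct effect of SAUR41 also stays open.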

How the results depend on the processing

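The gene length correction, library weights, crossed numbers and calls against each Col-0 shoot library alone were chosen after seeing the data. SAUR41 kept its direction and call in all alternatives, with log2 fold changes over single omissions of 9.40 to 10.18 in roots and 10.14 to 10.78 in shoots. Of the alternative values of other named genes, 877 kept direction and side of the threshold, 49 passed it, 23 no longer passed and 3 changed sign. The cause was not tested for any change below unless stated.

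Root calls were 1, and 3 with a pseudocount of 0.1, 3 with 5, 9 with no filter, 3 with the length correction, 14 with library weights and 8 with root libraries alone. Shoot calls were 4, and 30 (11 higher, 19 lower) with a pseudocount of 0.1, 17 (5, 12) with 5, 8 (1, 7) with no filter, 19 (8, 11) with a filter at 5 FPKM, 24 (19, 5) with quantile normalization, 4 (4, 0) with TMM scaling, 1 with no trend, 125 (70, 55) with the length correction, 1 with library weights, 1 with shoot libraries alone, and 211 against each Col-0 shoot library alone, which include 94 of the 125. Interaction calls were 0, and 2 with no filter. Tissue calls were 13094 (80.0% higher in roots), and 8369 (48.2%) with TMM scaling, 9982 (56.6%) with quantile normalization and 8309 with Col-0 libraries alone. The overlap was 1, and 2 with the length correction. Root lists called were 7, and 1 with an estimated correlation, 2 with directional fry and 3 with mixed fry. The SAUR41 subfamily, called through SAUR41 itself, is among the 7 and among those of both fry tests. Shoot lists called were 13, and 5 with quantile normalization, 0 with an estimated correlation and 3 with directional fry.

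Over single omissions, calls ranged from 1 to 9 in roots, 1 to 9864 in shoots, 0 to 6888 in the interaction and 7845 to 16335 between tissues, the overlap from 1 to 5, root lists from 4 (without OE-SAUR41 root 1) to 14 (without OE-SAUR41 root 2) and shoot lists from 8 (without Col-0 shoot 2) to 13. The sign changed for NIA1 (AT1G77760) in shoots, -0.12 without Col-0 shoot 2 and 1.13 without Col-0 shoot 1, for PRP3 (AT3G62680), -0.23 and 0.72 without OE-SAUR41 shoot 1 and 2, and for MYB29 (AT5G07690), 0.079 and -1.52 without Col-0 shoot 1 and 2.

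The labels give no shared origin for equal replicate numbers. Deviations of same-numbered libraries had a correlation across genes of 0.08 between the root groups, -0.005 between the shoot groups and 0.46 between OE-SAUR41 roots and Col-0 shoots. With the replicate block there were 1 root, 1 shoot, 0 interaction and 13522 tissue calls and 8 root and 12 shoot lists. Between Col-0 roots and shoots it was -0.22, and crossed numbers gave 12359 tissue calls. Depth is unknown, so its limits could not be set.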

Other observations

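All tests in this part were chosen after the patterns they address were seen. The Col-0 shoot libraries differed across most genes, and 3 technical explanations were tested. Root tissue in Col-0 shoot 1 is argued against by 24 genes abundant in roots. They had at least 100 FPKM in both Col-0 root libraries and under 1 FPKM in each other shoot library. In Col-0 shoot 1 they stood at a median of 0.152% of their Col-0 root level. A single scaling factor set by a few abundant genes would shift all genes alike, and it is argued against by an interquartile range of differences 2.62 times the largest of the other groups. Recovery of transcripts that depends on gene length stays open: the difference rose with gene span (Spearman rho 0.613 across genes), which is consistent with RNA degradation or library preparation that differed between the libraries. A trend with span was not particular to this pair: rho was -0.358 between the Col-0 root libraries, 0.312 between the OE-SAUR41 root libraries and -0.015 between the OE-SAUR41 shoot libraries, where the interquartile ranges of the differences were 0.30, 0.41 and 0.34, against 1.08 in Col-0 shoots. On the first 2 principal components, Col-0 shoot 1 lay apart, at -91.9 and 93.1. Col-0 shoot 2 (-154.0 and -19.7) lay near OE-SAUR41 shoots 1 (-148.5 and -28.0) and 2 (-147.1 and -25.8). The median was 6.24 FPKM in Col-0 shoot 1, 3.26 in Col-0 shoot 2, and 3.71 and 3.66 in OE-SAUR41 shoots. The OE-SAUR41 libraries are of another genotype, so this does not settle which Col-0 library is closer to the tissue. No biological explanation was tested, since both libraries carry the same labels.

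Of 92 genes with a mean of at least 100 FPKM in Col-0 roots and under 5 FPKM in both Col-0 shoots, 56 had a positive log2 fold change in OE-SAUR41 shoots, with a median of 0.11. The median lay 0.40 above that of all genes for the 88 with a span, largely because the median of all genes was negative (-0.32). The choice of genes low in Col-0 shoots, which can hardly fall, is argued against as the whole cause: each gene was set against 20 genes of like Col-0 shoot level with under 20 FPKM in Col-0 roots. Those had a median of -0.37, and the median difference was 0.56 (quartiles 0.042 and 0.996); gene length was not matched. Root tissue of all zones in the OE-SAUR41 shoot libraries may be a candidate source, but it would raise all 92 alike. The median rise was 0.0644% of the root level, 53 genes were at 0.2% or less and 19 at 1% or more. Tissue bearing root hairs is argued against as the whole cause by a median rise of -0.128% of the root level over the 6 root hair genes with at least 20 FPKM in Col-0 roots. Over all 15 the median was 0% (quartiles -0.128% and 0.0751%). LRX2, singled out after its values were seen, rose by 12.2% of its root level (0.57 to 2.17 FPKM, against 13.06 FPKM in Col-0 roots), and no other gene of the list by 1% or more. The list was called higher in shoots by camera (adjusted p = 0.0106; adjusted p = 0.607 with an estimated correlation) with a median log2 fold change of 0, against -0.32 for all genes. A trend with gene length is argued against as the whole cause, since the relative median was 0.32 with that trend removed (lower quartile 0.05). Tissue of another zone, such as the root base or hypocotyl, and a difference of genotype both stay open and were not tested.

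A further pattern, SAUR genes lower in OE-SAUR41 shoots, was tested first and replaced by the one above after its values were seen. With the length correction the relative median of other SAUR genes in shoots was -0.50 (camera adjusted p = 1.52e-05; adjusted p = 0.210 with an estimated correlation). Of the 30 genes not assigned to tandem clusters, 12 were lower adjusted over the list alone and the relative median was -0.024. Some of the 30 also lie beside another gene of the list, so they are not all single genes. For these 30 genes the p of camera in limma, not adjusted, was 0.0320. Of the 12 genes assigned to tandem clusters, 7 were lower, with a relative median of -0.34. The 6 evening clock genes had relative medians of -0.57 in shoots and -0.05 in roots.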
